A study of Homo sapiens and Mus musculus with 65 samples.

How the data were processed

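The series holds RNA and chromatin measurements on WDR5, a WD40-repeat protein of several chromatin complexes. RNA was measured in CHP134 neuroblastoma cells treated with C6, C38b, dTAG47 or DMSO, in LoVo colorectal cancer cells treated with C6 or DMSO, and in MV4:11 leukaemia cells treated with venetoclax, C10, both or DMSO. WDR5 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in human LoVo and Be2C cells and in mouse MC38 and 3T3 cells. Groups were taken from the sample labels, each with 3 libraries, except 4 per group in MV4:11 and 2 in LoVo ChIP-seq. The series' design text calls the ChIP-seq, SLAM-seq and 1 day CHP134 replicates biological. For the other groups nothing says that replicates came from separate cultures, so p-values there measure the spread between those samples, which may be technical.

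The RNA tables hold whole-number counts of reads per gene as deposited, not normalized. The submitters' processing notes name STAR, featureCounts and DESeq2 for RNA, without versions, and the builds hg19 and mm10. The notes do not tie a tool to a table, and strand handling was not given in the sources used here. CHP134 counts came in 3 deposited tables: C6 and DMSO at 1 and 4 days over all gene types, dTAG47 and its DMSO over protein-coding genes, and a protein-coding table that holds C38b beside the C6 and DMSO libraries. The MV4:11 table was deposited with newer gene versions, and its build was not given in the sources used here. SLAM-seq, which marks new RNA with a thiol-labelled nucleotide read as T>C conversions, was deposited as counts per gene in the column layout of slamdunk: all reads, reads with T>C conversions, converted T and covered T. Of the sample columns in the protein-coding table, 3 matched no sample of the series and were not used.

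WDR5 peaks were deposited per sample in the narrowPeak layout. Per the submitters' processing notes the tools for this assay were Bowtie2, MACS2 and DiffBind. The fold enrichment of each peak is a ratio given by the authors' peak caller, and the deposited −log10 q was just above 2 for the weakest peak of every list. These peak values are the authors' and served only to describe, rank or filter peaks within a list. Peak lists were used for the WDR5 samples alone. The IgG samples were not used here.

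Total counts per library were 18142706 to 27669323 for CHP134 C6 and DMSO, 29533325 to 39221453 for dTAG47, 16519920 to 21084075 for C38b and 21621114 to 37704503 for MV4:11. In LoVo they were 20478365 to 30140014 reads, of which 1515906 to 2314240 carried T>C conversions. The T>C counts are the shallowest data here. In simulated LoVo T>C counts over 10057 genes, a mean of 47.8 of 100 planted changes of log2 1 and 10.8 of 100 of log2 0.5 were recovered over 5 draws, so small changes in new RNA were often not detectable at this depth. No replicate pair agreed within sampling noise by chi-square, so all libraries counted as separate samples.

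Differential expression was tested from the counts with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test, after TMM normalization and the filterByExpr filter (minimum count 10), with group means and no covariates. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Unless another test is named, an adjusted p in the text is of this test. The 12 CHP134 C6 and DMSO libraries shared a fit, as did the 16 MV4:11 libraries. C38b was tested against DMSO at 1 day in the protein-coding table, and against C6 at 1 day in a fit of 9 libraries with that DMSO. T>C counts were tested with the totals and TMM factors of all reads, so that a general fall in new RNA would remain visible. CPM values were computed from the deposited counts and scaled by the TMM factors, given as mean ± SD with n = 3, or n = 4 in MV4:11.

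The 25 gene lists were fixed before the data were examined: cytosolic ribosomal proteins, translation factors, ribosome biogenesis, small nucleolar RNA host genes, mitochondrial ribosomal proteins, aminoacyl-tRNA synthetases, p53 targets, integrated stress response targets, cell cycle, cholesterol synthesis, interferon-stimulated genes, WDR5 complex partners, adrenergic and mesenchymal neuroblastoma identity, BCL2 family, MLL fusion targets, myeloid differentiation, WNT targets, immediate early genes, nuclear respiratory chain genes, mitochondrially encoded mRNAs, histones, and epithelial, lymphoid or erythroid, and fibroblast markers. Each list was described by the members called, by members called when adjusted over the list alone, by its median log2 fold change, and by camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation. The preset is the more lenient: 85 list results past p 0.05 with it were not past it with an estimated correlation, and 224 stayed on the same side. List p-values below are camera p-values with the estimated correlation. A list adjusted p is this p after Benjamini-Hochberg adjustment over the 23 to 25 lists of its comparison, an adjustment added after the results were seen. With it no list passed 0.05 in any CHP134 or LoVo comparison, and lists passed only in MV4:11. Histone and mitochondrial lists served also as signs of library composition, and the protein-coding tables held 1 member of the small nucleolar RNA host list.

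Genes named in the text followed a rule fixed before the data were examined: in each main comparison the 4 largest rises and 4 largest falls among called genes whose groups did not overlap and whose mean was at least 5 CPM, then the members of fixed lists with the smallest p, always WDR5, and BCL2 in MV4:11. Other comparisons gave the 2 largest rises and falls, and for interactions, which involve 4 groups, separation of the groups was not asked for. Some genes given by this rule are not reported here, and no others took their places. RPS10 and RPL17 overlap readthrough genes and HSPA1B has near-identical copies, so their levels are uncertain, and the LoVo table shares EEF1G with a second gene name.

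Consensus WDR5 regions were merged peaks found in at least 2 replicates, overlapping by at least 1 bp. A human gene was called bound when a consensus region lay within 1000 bp of either end of its deposited hg19 coordinates, since strand was not used, among 17510 protein-coding genes. The plan had named the transcription start, and gene ends took its place because no annotation of that build was used here. No mouse annotation was used here, so mouse regions were not assigned to genes and the planned comparison of bound genes between species was not run. Enrichment of lists and overlaps of called genes were tested with Fisher's exact test, two-sided (SciPy 1.17.1 under Python 3.11.15). Fold changes against shared DMSO libraries were compared with 10 simulations of unchanged groups.

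Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, only the compared groups in the fit, the replicate number as a block, leaving out each library, T>C counts scaled by themselves or by the gene's own total reads, stricter or other peak definitions, and an adjusted p under 0.01 for overlaps. Added after seeing the data were the other control time for C6 at 4 days and for C38b, protein-coding genes only, a larger peak overlap for bound genes, and RLE for ribosomal protein genes with and without a peak. Same-numbered libraries deviated together in every pair for C6 against DMSO at 4 days (r 0.143 to 0.289 across genes) and for dTAG47 (r 0.107 to 0.25). Their numbers were therefore treated as pairing the samples when the block and the splits were read. The main fits for them stayed unpaired. This pairing comes from the data, not from the labels. In the other comparisons the numbers did not pair the libraries. Each kind of test was run on simulated counts with 200 changed genes. Single draws with 2 other seeds had given differing results, so 5 new draws were made, of which the text gives the mean and the range. The mean share of false calls, with the lowest and highest draw, was 11.9% for C38b (10.8% to 13.1%), 8.42% for dTAG47 (6.47% to 14.7%), 8.29% for C6 at 4 days (4.29% to 10.1%), 7.71% for C6 at 1 day (5.19% to 10.2%) and 6.55% for all LoVo reads (4.88% to 8.97%). These means exceed the nominal 5%, so more of the calls there may be false than the threshold states. The means were 4.18% for the MV4:11 interaction (2.31% to 5.88%), 4.04% for C10 (1.76% to 6.67%) and 2.69% for LoVo T>C reads (0% to 8.57%).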

Results

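WDR5 is a WD40-repeat protein that takes part in histone methyltransferase complexes and binds many chromatin regulators through its WIN site, a pocket that the series describes as the target of C6. RNA was counted in CHP134 neuroblastoma cells after C6 (5 uM) or DMSO for 1 or 4 days, after C38b (5 uM), and after dTAG47 (500 nM), a degrader of tagged proteins, with its own DMSO (n = 3 per group). The labels do not name the tagged protein or the dTAG47 time, and they give conflicting times for C38b. New RNA was counted by SLAM-seq in LoVo colorectal cancer cells after 4 h of C6 (25 uM) or DMSO (n = 3). MV4:11 leukaemia cells received DMSO, the BCL2 inhibitor venetoclax (50 nM), C10 (100 nM), or both drugs (n = 4). WDR5 peaks were deposited for LoVo (n = 2), Be2C neuroblastoma, and the mouse lines MC38 and 3T3 (n = 3 each). Libraries held 16519920 to 39221453 counts, apart from the T>C reads of SLAM-seq, which numbered 1515906 to 2314240 per library.

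To find the genes that carry WDR5, peaks shared by replicates were assigned to human genes. WDR5 lay at 135 of 17510 protein-coding genes in LoVo and at 116 in Be2C, and the genes for cytosolic ribosomal proteins stood out among them. Of 79 ribosomal protein genes, 43 (54.4%) were bound in LoVo and 42 (53.2%) in Be2C, against 0.771% and 0.663% of all genes (Fisher's exact test, adjusted p = 2.34e-71 and 4.66e-72). Translation factor genes were bound above the background, with 5 of 43 in each line (adjusted p = 8.66e-05 and 5.53e-05). Mitochondrial ribosomal protein genes had 0 bound of 76 in LoVo and 1 of 76 in Be2C (adjusted p = 1.0). No protein-coding gene of the ribosome biogenesis, aminoacyl-tRNA synthetase, respiratory chain, cell cycle or cholesterol lists was bound in either line. Binding at small nucleolar RNA hosts was not analysed here beyond 1 protein-coding member, which was not bound. The lines shared 100 bound genes where 0.894 were expected for independent sets (p = 2.73e-215, exact test), and 42 of the shared genes encode ribosomal proteins, while RPL36 was bound in LoVo alone.

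The LoVo regions with the highest mean fold enrichment over background, in hg19 coordinates, were chromosome 7 from 915717 to 916304 near GET4 and SUN1 (26.0-fold), chromosome X from 118924988 to 118926127 at the ribosomal protein gene RPL39, and chromosome 4 from 109541501 to 109542281 at RPL34 (24.6-fold). In Be2C they were chromosome 17 from 80231067 to 80231690 at the casein kinase gene CSNK1D (35.6-fold), chromosome 16 from 2317618 to 2318305 at the splicing gene RNPS1 (34.1-fold), and chromosome 19 from 3984975 to 3985583 at EEF2, the translocation factor of translation elongation (32.6-fold). Replicates held very different numbers of peaks. LoVo replicates had 2174 and 122 peaks and shared 120 consensus regions, and Be2C replicates had 117, 93 and 250 peaks and gave 121 regions. When peaks had to overlap by at least 50% of both, LoVo kept 63 regions and 25 bound ribosomal protein genes, the latter an alternative chosen after seeing the data.

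In mouse cells WDR5 consensus regions were more numerous, with 2871 in MC38 and 2429 in 3T3. MC38 replicates had 5968, 3569 and 2571 peaks and 3T3 replicates 1799, 5939 and 2456. LoVo replicate 1 had 2174, and the LoVo consensus is limited by the 122 peaks of replicate 2. A difference in peak yield between experiments therefore cannot be told from a difference between species. About 40.5% of the MC38 regions (1164) overlapped a 3T3 region, and 47.9% of the 3T3 regions overlapped an MC38 region. The highest MC38 regions in mm10 were chromosome 11 from 97781655 to 97782765 (45.9-fold), chromosome 2 from 158360937 to 158361878 (45.8-fold) and chromosome 11 from 120990756 to 120991514 (45.3-fold). Those in 3T3 were chromosome 11 from 101442157 to 101443326 (52.5-fold), chromosome 11 from 75732456 to 75733884 (52.2-fold) and chromosome 8 from 110845983 to 110847162 (51.9-fold). Leaving out MC38 replicate 1 left 1818 regions, and leaving out 3T3 replicate 2 or 3 left 1316 or 1482.

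To ask which genes change in new RNA soon after WIN site inhibition, T>C reads were compared in LoVo after 4 h of C6. The 4 largest rises under the naming rule were in metallothionein genes, which encode metal-binding proteins and were not a fixed list. MT1G went from 2.51 ± 0.514 to 93.4 ± 12.7 CPM (log2 fold change 5.21 ± 0.142 SE, n = 3, adjusted p = 2.49e-38). MT2A went from 53.3 ± 6.71 to 692 ± 51.4 CPM, and MT1F and MT1M rose by 3.85 and 3.98 on the log2 scale. New RNA of many ribosomal protein genes fell. RPL26 went from 183 ± 4.33 to 93.7 ± 13.4 CPM (−0.97 ± 0.0891, adjusted p = 1.44e-12), and RPL27 (−1.03), RPL37A (−0.96) and RPL32 (−0.95) fell too. Of 79 ribosomal protein genes 43 fell, or 74 when adjusted over the list alone, and 0 rose (median −0.51). Against the other genes the list had p = 0.00577 by camera with an estimated correlation, but it no longer passed when adjusted over lists (list adjusted p = 0.133). No list passed with that adjustment in any LoVo or CHP134 comparison, so list statements there only describe the genes counted. A list whose share of called members is near that of all genes in its comparison does not stand out. Ribosomal protein genes took 11.0% to 11.7% of the T>C reads in DMSO libraries and 8.08% to 9.31% after C6.

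Elongation factors EEF1G (−1.04 ± 0.105), EEF2 (−0.47 ± 0.0845) and EEF1D (−0.55 ± 0.133), the kinase gene CSNK1E (−1.15), the RNA-binding protein gene KIAA0907 (−1.01) and the lysyl-tRNA synthetase gene KARS (−0.57) also fell in new RNA. The respiratory chain list had 3 of 73 members lower, COX7C among them (−0.52), or 14 when adjusted over the list alone (median −0.28, list adjusted p = 0.524). Translation factors had 2 lower of 41 and aminoacyl-tRNA synthetases 1 of 22, and no list gained a called member. Among lists with 0 called members, the medians were −0.04 for p53 targets, −0.07 for ribosome biogenesis, −0.13 for mitochondrial ribosomal proteins, 0.08 for the cell cycle, 0.11 for WNT targets and −0.05 for epithelial markers. FDXR, a p53 target, had a log2 fold change of −0.41 (adjusted p = 0.749), and WDR5 itself 0.24 ± 0.206 (adjusted p = 0.878). The share of reads with T>C conversions was 7.75% ± 0.231 in DMSO and 7.68% ± 0.28 after C6 (n = 3, exact permutation p = 0.8, two-sided, smallest possible 0.1).

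By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13 genes rose and 64 fell in T>C reads of 10057 tested. Scaled by each gene's own total reads the counts were 8 and 35. KIAA0907 (−0.27, adjusted p = 0.919), COX7C (−0.24, adjusted p = 0.648), KARS (adjusted p = 0.11), EEF1D (adjusted p = 0.0748) and CSNK1E (adjusted p = 0.0692) then no longer passed. Calls for 4 named genes each ended when a single library was left out: COX7C without C6 replicate 2 (adjusted p = 0.208) or DMSO replicate 3 (0.137), EEF1D without DMSO replicate 1 (0.317), C6 replicate 3 (0.135) or C6 replicate 2 (0.0864), and KIAA0907 without DMSO replicate 1 (0.43), C6 replicate 2 (0.133) or C6 replicate 1 (0.067). The call for KARS ended without any of the libraries except C6 replicate 2, the adjusted p then ranging from 0.0852 to 0.228.

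All reads of the same LoVo libraries were compared too. MT1G rose from 34.1 ± 1.02 to 239 ± 20.2 CPM (2.81 ± 0.0722, n = 3, adjusted p = 2.35e-24) and MT1F by 2.45 on the log2 scale, while NDUFB1, a respiratory chain gene, and RNF220, a ubiquitin ligase gene, fell (−0.44 and −0.42). Of 79 ribosomal protein genes 16 fell, or 65 when adjusted over the list alone (median −0.20, p = 0.0268 with an estimated correlation, list adjusted p = 0.586), and 8 of 73 respiratory chain genes fell (list adjusted p = 0.586). In all, 14 genes rose and 34 fell of 11854 tested. The lower count was 8 without C6 replicate 1, 101 without C6 replicate 3, and 12, 5 and 14 without DMSO replicates 1, 2 and 3. The higher count was 9 without DMSO replicate 2, and 39 with no filter on low counts. RNF220 no longer passed without DMSO replicate 2 (adjusted p = 0.129), DMSO replicate 1 (0.119), C6 replicate 1 (0.0761) or C6 replicate 2 (0.0523).

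CHP134 cells were then compared after 1 day of C6, at 5 uM. Few genes changed, and ribosomal protein genes were among those that fell: RPS10 went from 15.7 ± 1.42 to 5.95 ± 0.28 CPM (−1.40 ± 0.141, n = 3, adjusted p = 0.000313), RPL17 from 27.5 ± 0.859 to 13.4 ± 1.09 CPM (adjusted p = 0.00916) and RPL8 from 746 ± 86.2 to 485 ± 42.3 CPM (adjusted p = 0.043). SNHG15, a host of small nucleolar RNAs, fell from 48.3 ± 2.98 to 22.5 ± 0.796 CPM (−1.10 ± 0.116), as did SNHG17 (−0.71) and KLB (−0.97), a coreceptor for fibroblast growth factors. LMO3, a transcriptional cofactor known in neuroblastoma, rose from 5.81 ± 0.524 to 11.2 ± 0.975 CPM (0.94 ± 0.135, adjusted p = 0.0092), and TEX15, the glutamate transporter SLC1A3 and the helicase gene DDX25 rose by 0.72, 0.58 and 0.50 on the log2 scale. Ribosomal protein genes had 3 of 76 lower, or 16 when adjusted over the list alone (median −0.29, p = 0.179 with an estimated correlation, list adjusted p = 0.909), and small nucleolar RNA hosts had 2 of 15 lower. None of the other lists had a called member. WDR5 had a log2 fold change of 0.02 ± 0.0785 (adjusted p = 0.96).

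The 1 day count, 6 higher and 25 lower of 19291 genes, depended strongly on the fit. With only the compared groups it was 626 and 574, with DESeq2 59 and 58, with no filter on low counts 47 and 102, and 2150 genes had an unadjusted p under 0.05. Without any one of the 6 compared libraries (C6 replicates 1, 2 or 3, DMSO replicates 1, 2 or 3) it was 0 or 1 higher and 3 to 5 lower. RPL17, RPL8, SNHG17, KLB, TEX15, SLC1A3 and DDX25 each missed the threshold without any one of these 6, with adjusted p from 0.0504 to 0.335. LMO3 missed it without all but C6 replicate 1 (0.0616 to 0.113), while RPS10 and SNHG15 passed each time.

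After 4 days of C6 much of the transcriptome differed from DMSO of the same day. RPL29 went from 652 ± 48.3 to 188 ± 46.3 CPM (−1.80 ± 0.155, n = 3, adjusted p = 7.11e-07), and RPL17 (−2.10) and RPL8 (−1.26) fell too. EEF2 went from 5452 ± 396 to 2218 ± 165 CPM (−1.30 ± 0.131). Of 76 ribosomal protein genes 67 fell and 0 rose, or 68 when adjusted over the list alone (median −1.25, p = 0.0702 with an estimated correlation, list adjusted p = 0.396). Of 41 translation factor genes 23 fell, EIF3D (−1.03), and 1 rose (list adjusted p = 0.396). Of 31 ribosome biogenesis genes 15 fell, POLR1B (−0.84), and 1 rose (list adjusted p = 0.396). Small nucleolar RNA hosts had 14 of 15 lower, SNHG15 (−1.95) and EPB41L4A-AS1 (−1.32) (median −0.89, list adjusted p = 0.197). Mitochondrial ribosomal protein genes had 31 of 75 lower, MRPL44 (−0.96), and 4 higher (list adjusted p = 0.678).

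After 4 days of C6, 15 of 26 p53 targets rose and 1 fell (median 0.51, list adjusted p = 0.0773). CDKN1A, the inhibitor of cyclin-dependent kinases, went from 25.0 ± 0.91 to 114 ± 6.58 CPM (2.19 ± 0.0837, n = 3, adjusted p = 1.14e-10), and TP53INP1 rose by 1.52. Cell cycle genes fell in 18 of 26 cases with 0 higher (median −0.54, list adjusted p = 0.197), among them cyclin A2 (CCNA2), from 222 ± 22.8 to 95.2 ± 13.6 CPM, and 32 of 52 histone genes fell (list adjusted p = 0.668). SESN2, a stress response gene, rose from 20.1 ± 4.3 to 82.5 ± 12.4 CPM, and 7 of 15 stress response targets rose with 3 lower (list adjusted p = 0.396). Of 19 adrenergic identity genes 6 rose, CHGB by 0.54, and 2 fell (list adjusted p = 0.678). Of 14 mesenchymal genes 5 rose, FOSL2 by 1.16, and 1 fell, TWIST1 (−1.02). BCL2 family genes had 7 higher and 4 lower of 14. Other lists moved both ways: aminoacyl-tRNA synthetases 5 higher and 7 lower of 21 (MARS 0.64), cholesterol synthesis 3 and 4 of 15, interferon-stimulated genes 3 and 3 of 8 (IFI44 −0.78), WDR5 complex partners 2 and 5 of 16 (DPY30 −0.61), immediate early genes 1 and 5 of 10 (JUN −1.55) and respiratory chain genes 8 and 15 of 70 (NDUFV2 −1.13). Of all 19291 genes tested 4948 rose and 4775 fell. The respiratory chain counts lay below these shares and those of several other lists near them, so such counts do not set a list apart. WDR5 itself had 0.18 ± 0.0796 (adjusted p = 0.0771).

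Under the naming rule, the 4 largest falls at 4 days were the heat shock genes HSPA6, HSPA1B, DNAJB1 and HSPB1. The 4 largest rises were MT-ND1, MTATP6P1, MT-CYB and MT-ND5. In both sets the DMSO libraries of the times differed too. Heat shock genes were not a fixed list and were not tested as a group. HSPA6, a heat-inducible chaperone, was at 1.01 ± 0.303 CPM after 4 days of C6 and 47.7 ± 9.98 in 4 day DMSO (−5.55 ± 0.2, n = 3, adjusted p = 1.14e-10), but at 3.85 ± 0.451 in 1 day DMSO. DNAJB1, an HSP40 cochaperone, was at 51.1 ± 6.61, 518.5 ± 82 and 94.3 ± 2.98 CPM in the same groups, and HSPA1B (−3.61) and HSPB1 (−2.71) also fell. MT-ND1 was at 150 ± 170 CPM after 4 days of C6, 15.4 ± 2.65 in 4 day DMSO (3.29 ± 0.738, adjusted p = 0.006) and 49.0 ± 2.59 in 1 day DMSO. MTATP6P1, MT-CYB and MT-ND5 rose by 3.22, 2.82 and 2.77, and all 13 mitochondrially encoded mRNAs rose (median 2.61, list adjusted p = 0.396). MTATP6P1 is not among these 13. C6 4 day replicate 3 had 1.321% of its protein-coding counts in these mRNAs, against 0.306% and 0.285% in the others, and 4.93% in ribosomal protein genes against 7.27% and 6.86%. Leaving replicate 3 out gave a median of 1.68 for the mitochondrial mRNAs.

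**Figure D1:**
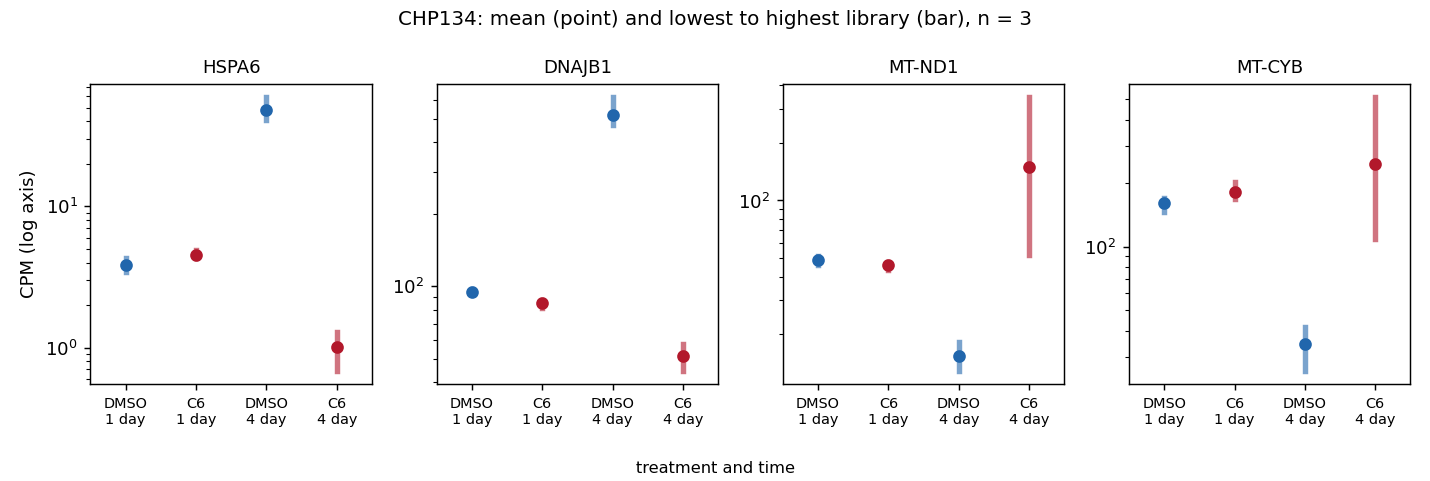
Levels of the heat shock genes HSPA6 and DNAJB1 and the mitochondrially encoded MT-ND1 and MT-CYB in CHP134 cells, in CPM on a log axis, for DMSO and C6 at 1 and 4 days; points are means and bars run from the lowest to the highest of 3 libraries. HSPA6 stands at 47.7 CPM in 4 day DMSO and at 1.01 to 4.52 CPM in the other groups.

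At 4 days 4948 genes rose and 4775 fell of the genes tested. As an alternative chosen after seeing the data, the 4 day C6 libraries were set against 1 day DMSO, which gave 4067 and 3966. Ribosomal protein genes then had 38 lower and 7 higher (median −0.50), translation factors 15 lower and 13 higher (median −0.12), p53 targets 17 higher and 4 lower, cell cycle genes 21 lower, histones 45 lower, and small nucleolar RNA hosts 5 each way. Against that control EEF2 (0.08) no longer fell, NOB1 changed from −0.71 to 0.82, EPB41L4A-AS1 from −1.32 to 0.78, FOSL2 from 1.16 to −0.49, CHGB from 0.54 to −0.09 and NDUFV2 from −1.13 to 0.21 (the last pair not passing), WDR5 had −0.51, and EIF3D, HSPB1, IFI44, JUN, POLR1B, MTATP6P1 and the mitochondrial genes named no longer passed. The DMSO groups themselves differed by 5064 genes higher and 5230 lower at 4 days, so a difference between the controls of the times is part of this comparison.

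Whether the C6 response differed between times was tested as an interaction. The log2 effect was higher at 4 days for 3611 genes and lower for 3795, with HSPA6 (−5.78 ± 0.268, adjusted p = 5.39e-09), HSPA1B (−3.67), MT-ND1 (3.38, adjusted p = 0.0261) and MTATP6P1 (3.38) the largest. Ribosomal protein genes had 53 of 76 lower, or 58 when adjusted over the list alone (median −0.79, list adjusted p = 0.499), and p53 targets 12 of 26 higher and 1 lower (list adjusted p = 0.202). MT-ND1 no longer passed without DMSO 4 day replicate 1 or 2 or without C6 1 day replicate 1, 2 or 3 (adjusted p 0.0517 to 0.0593). Each time has its own DMSO, so the differences between DMSO groups enter here as well.

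After dTAG47 many genes changed by small amounts. DHRS2, a dehydrogenase gene, rose from 3.92 ± 0.387 to 20.2 ± 1.74 CPM (2.37 ± 0.0979, n = 3, adjusted p = 6.1e-11), followed by the adhesion genes CDH6 (1.30) and CADM2 (1.28) and SESN3 (1.21). The retinoic acid receptor gene RARG fell from 15.9 ± 0.738 to 6.76 ± 0.254 CPM (−1.23 ± 0.0821), with SYDE1, CTDSP1 and GAS2L1 (−1.26, −1.24 and −1.14). RPL7 fell from 759 ± 20 to 516 ± 7.42 CPM (−0.56 ± 0.0355), as did RPL6 (−0.53), RPS3A (−0.54) and EEF2 (−0.28). Ribosomal protein genes split, with 41 of 74 lower and 11 higher, or 18 higher when adjusted over the list alone (median −0.24, list adjusted p = 0.87). Translation factors had 10 higher and 5 lower of 41, EIF4G3 among the lower (−0.30), and ribosome biogenesis genes 6 higher and 0 lower of 31, RRP12 by 0.23 and GNL3 by 0.13. Adrenergic genes had 6 of 19 higher and 0 lower (median 0.11, list adjusted p = 0.87), among them the receptor kinase gene ALK, from 20.1 ± 0.978 to 31.6 ± 1.24 CPM, and ISL1 (0.49). Mesenchymal genes had 6 of 15 lower, SPARC (−0.82) and NOTCH3 (−1.02), and 1 higher (list adjusted p = 0.87).

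The dTAG47 response of p53 targets went both ways, with 4 higher and 7 lower of 25, TP53INP1 at 0.45 and TP53I3 at −0.44, and 20 of 49 histone genes fell with 2 higher (list adjusted p = 0.87). Stress response targets had 5 higher and 6 lower (PHGDH −0.70), cell cycle genes 2 and 6 of 26 (AURKA −0.30), BCL2 family genes 2 and 6 of 14, mitochondrial ribosomal proteins 5 and 12 of 75 (MRPL35 −0.54) and WDR5 complex partners 5 and 1 of 15 (SETD1B 0.25). JUN rose by 0.42, EPRS by 0.19 and NDUFS1 by 0.15, while DHCR7 (−0.24) and the interferon-stimulated IFI6 (−0.53) fell. WDR5 mRNA had −0.03 ± 0.0417 (adjusted p = 0.671). In all, 2180 genes rose and 2682 fell of 13514, of which 82 and 112 changed at least 2-fold. The counts of mitochondrial ribosomal protein genes lay below the shares of all genes, so they do not set that list apart. GNL3 no longer passed without dTAG47 replicate 3 (adjusted p = 0.0622), nor IFI6 without dTAG47 replicate 1 (0.0776), dTAG47 replicate 2 (0.087) or DMSO replicate 2 (0.0544).

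C38b was set against 1 day DMSO. CPEB2, a regulator of mRNA translation, rose from 6.17 ± 0.79 to 16.5 ± 1.27 CPM (1.41 ± 0.131, n = 3, adjusted p = 0.000366), and IDS and TXNIP rose by 1.28 and 1.23 on the log2 scale. RPS10 fell from 20.8 ± 1.8 to 6.10 ± 1.57 CPM (−1.78 ± 0.176), RPL17 from 36.3 ± 0.969 to 14.9 ± 0.908 CPM and RPL36 from 503 ± 59.1 to 283 ± 27.1 CPM, with the mitochondrial creatine kinase gene CKMT1A (−1.59), CABP7 (−1.57) and ATHL1 (−1.54). Ribosomal protein genes had 37 of 74 lower and 1 higher, RPS16 (1.35 ± 0.33, adjusted p = 0.0222), or 3 higher when adjusted over the list alone (median −0.37, list adjusted p = 0.84). Translation factors had 13 of 41 higher, EIF1AX by 0.73 and EIF3J by 0.62, and 3 lower (list adjusted p = 0.572). Ribosome biogenesis genes had 4 higher, DDX21 by 0.53. TAF1D rose by 0.67. Cell cycle genes had 8 of 26 higher and 0 lower, MCM6 by 0.59 (median 0.19, list adjusted p = 0.498), adrenergic genes 6 of 16 higher, STMN2 by 0.62 and ISL1 by 0.72 (list adjusted p = 0.498), and cholesterol synthesis genes 5 of 15 higher (list adjusted p = 0.521). Mesenchymal genes had 2 higher, VIM by 0.92, and 3 lower, NOTCH3 (−1.91), and p53 targets 3 each way, with FDXR (−0.73) and BAX (−0.47) lower. MRPL42, GARS, PSAT1, KLF6 and NDUFC2 rose by 0.52, 0.37, 0.51, 0.84 and 0.56, IFI6 fell by 0.65, and WDR5 had 0.06 ± 0.0769 (adjusted p = 0.566).

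The C38b count was 1675 higher and 1790 lower of 12742 genes. Without DMSO 1 day replicates 1, 2 and 3 it was 871, 543 and 1010 higher and 1056, 727 and 978 lower, without C38b replicate 2 1143 lower, and without C38b replicate 3 2941 and 2998. C38b replicate 3 had 0.654% of its protein-coding counts in mitochondrial mRNAs, against 0.268% and 0.291% in the others. Against 4 day DMSO, an alternative chosen after seeing the data, 3983 rose and 3858 fell, and BAX (0.44), GARS (−0.50), NOB1 (−1.13, from 0.34), PSAT1 (−0.47) and TAF1D (−0.60) took the opposite sign. DDX21 (0.12, adjusted p = 0.308) and STMN2 (0.10, adjusted p = 0.346) no longer passed against it. RPS16 no longer passed without DMSO replicate 2 (adjusted p = 0.0877) or 3 (0.0839), IDS without DMSO replicate 2 (0.0505), NDUFC2 without DMSO replicate 2 (0.0501), IFI6 without DMSO replicate 1 (0.0569) or 2 (0.0759), and NOB1 without any library except C38b replicate 3 (0.0516 to 0.113).

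C38b and C6, given at the same dose, were compared directly with C6 at 1 day. DKK1, a secreted WNT inhibitor, was higher with C38b, at 14.6 ± 0.876 against 6.61 ± 0.59 CPM (1.14 ± 0.118, n = 3, adjusted p = 0.00108), as was ZNF703 (1.05 ± 0.252, adjusted p = 0.0385). BZRAP1 was lower, at 6.14 ± 0.353 against 13.9 ± 1.23 CPM (−1.19 ± 0.113), and GPRC5C had −1.13 ± 0.124. Cholesterol synthesis genes were higher with C38b in 4 of 15 cases, or 10 when adjusted over the list alone (median 0.24, list adjusted p = 0.0631), cell cycle genes in 3 of 26 (list adjusted p = 0.198), adrenergic genes in 2 of 16, or 5 over the list alone (list adjusted p = 0.198), and translation factors in 7 of 41, or 8 higher and 2 lower over the list alone (list adjusted p = 0.404). No ribosomal protein gene of 75 passed in edgeR's test of this difference. Their mean log2 CPM was 8.898 with C38b and 8.881 with C6, a difference of 0.02 (95% interval −0.21 to 0.25).

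Between the compounds 455 genes were higher and 516 lower with C38b of 12943, with 3181 at an unadjusted p under 0.05. Without C6 replicates 1, 2 and 3 the counts were 103, 184 and 163 higher and 121, 232 and 202 lower, without C38b replicates 1 and 2 320 and 294 lower, and without C38b replicate 3 1166 and 1195. ZNF703 missed the threshold without C6 replicate 1 (adjusted p = 0.136), 2 (0.0985) or 3 (0.0877). Since the time of C38b is not settled, C6 at 4 days was tried after seeing the data and gave 3294 higher and 3406 lower.

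To see how genes with a WDR5 peak responded, bound genes were compared with unbound ones. In LoVo T>C reads 40 of 119 bound genes fell against 24 of 9938 unbound (Fisher's exact test, adjusted p = 1.45e-62, camera p = 0.00333 with an estimated correlation). In CHP134, Be2C-bound genes fell in 7 of 106 cases after 1 day of C6 (18 of 19185 unbound, adjusted p = 6.48e-11), in 78 of 106 after 4 days (4697 of 19185, adjusted p = 1.97e-25), in 68 of 105 after dTAG47 (2614 of 13409, adjusted p = 2.45e-23) and in 48 of 106 after C38b (1742 of 12636). Genes bound in both human lines fell in MV4:11 in 65 of 92 cases after C10 (2385 of 13293 unbound, adjusted p = 2.76e-27), in 65 of 92 after both drugs (adjusted p = 1.72e-23) and in 28 of 92 after venetoclax (1174 of 13293, adjusted p = 4.11e-09), the last with p = 0.252 by camera with an estimated correlation. Without ribosomal protein genes the median of the bound genes was nearer 0 in each comparison. It went from −0.38 to −0.18 in LoVo T>C reads, from −0.12 to −0.03 in all LoVo reads, from −0.29 to −0.11 after 1 day of C6 and from −0.80 to −0.38 after 4 days. After dTAG47 it went from −0.24 to −0.12, after C38b from −0.29 to −0.14, after C10 from −0.45 to −0.14, after both drugs from −0.59 to −0.17 and after venetoclax from −0.06 to 0.02, where the fall no longer holds. With a peak in any replicate it was −0.07 in LoVo T>C reads. Binding in CHP134 and MV4:11 was not analysed here.

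Within the ribosomal protein genes, a split chosen after seeing the data set those bound in both human lines against the rest. The exact test takes genes measured in the same libraries as independent. Its p-values here describe the division of the genes and not the spread between samples. All 38 bound genes fell after dTAG47 (median −0.43), while 3 of 36 unbound ones fell and 11 rose (median 0.10, Fisher's exact test, adjusted p = 4.5e-17). C10 in MV4:11 left 41 of 42 bound genes lower (median −0.64) and 3 of 37 unbound ones lower with 21 higher (median 0.19). After C38b 33 of 39 bound genes fell against 4 of 35 (adjusted p = 4.5e-10), in LoVo T>C reads 36 of 42 against 7 of 37 (adjusted p = 2.7e-09), and after both MV4:11 drugs 41 of 42 against 9 of 37 (adjusted p = 4.74e-12). After 4 days of C6 all 39 bound genes fell, with a median of −1.54, and 28 of 37 unbound ones, with a median of −0.50 (adjusted p = 0.00131). In all LoVo reads 13 of 42 bound genes fell against 3 of 37 (adjusted p = 0.017), though the medians were close, at −0.22 and −0.18. After 1 day of C6, where few genes were called at all, 3 of 39 bound genes fell against 0 of 37 (adjusted p = 0.241). The medians there still lay apart, at −0.48 for bound and 0.06 for unbound genes. Venetoclax alone lowered 25 of 42 bound and 16 of 37 unbound genes (adjusted p = 0.201), with medians of −0.17 and −0.15. With RLE size factors the medians had the same signs, 37 of the 38 bound genes fell after dTAG47, and 16 unbound genes rose after dTAG47 and 21 after C10.

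**Figure D2:**
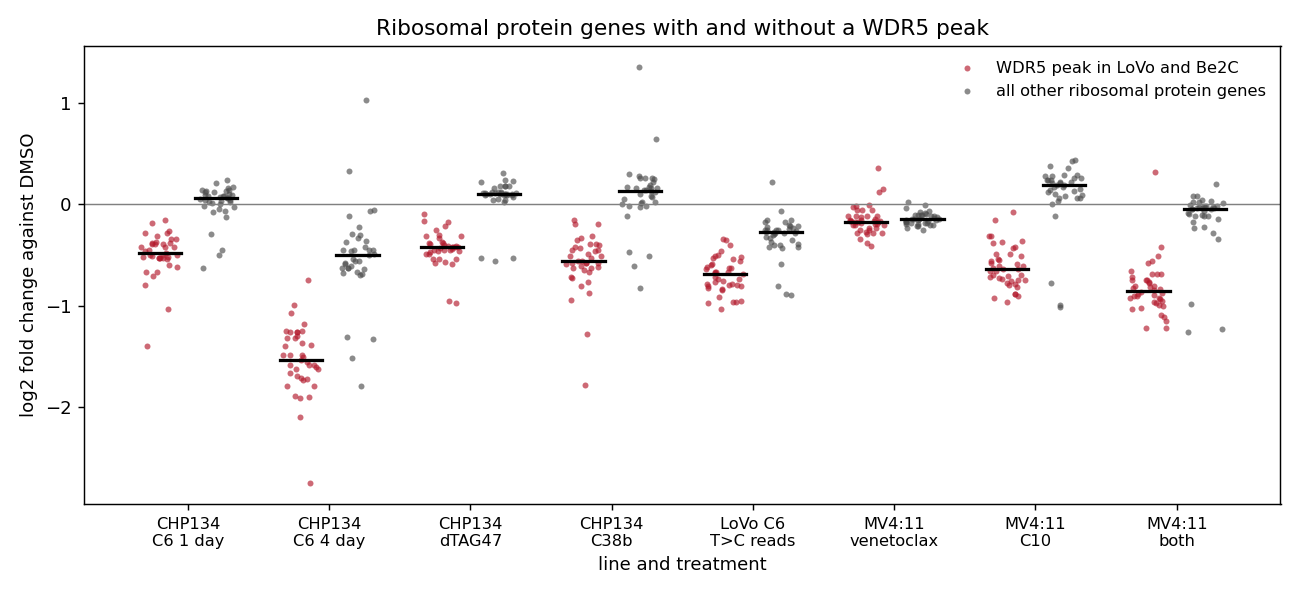
Log2 fold changes of cytosolic ribosomal protein genes in 8 comparisons with their controls; red points are genes with a WDR5 peak in both LoVo and Be2C, grey points are all other ribosomal protein genes, and black lines are medians. After dTAG47 the bound genes have a median of −0.425 and the others 0.102, and after C10 −0.639 and 0.189.

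Responses with separate controls were compared between lines and, for C6 and dTAG47, within CHP134. Genes lower after 1 day of C6 in CHP134 overlapped those lower after dTAG47 (15 shared, 3.66 expected for independent lists, Fisher's exact test, adjusted p = 4.37e-08) and after C10 in MV4:11 (13 shared, 2.97 expected). Genes lower in LoVo T>C reads shared 41 with dTAG47 (11.4 expected, adjusted p = 1.25e-16), 35 of them ribosomal protein genes, 45 with C10 (12.1 expected, adjusted p = 2.54e-19), 38 of them ribosomal, and 48 with 4 days of C6 (21.9 expected), 40 of them ribosomal. Between dTAG47 and C10, 514 lower genes (396 expected, adjusted p = 4.76e-12) and 415 higher genes (314 expected, adjusted p = 6.36e-11) were shared, and between 4 days of C6 and C10 860 lower (648 expected, adjusted p = 4.81e-27) and 562 higher (422 expected). Between 4 days of C6 and dTAG47 the overlap did not exceed independent lists, with 785 lower (822 expected, adjusted p = 0.133) and 454 higher (483 expected, adjusted p = 0.145).

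In MV4:11 cells venetoclax, which blocks the antiapoptotic protein BCL2, lowered the cholesterol synthesis genes as a group: all 15 fell (median −0.78, list adjusted p = 0.000755), INSIG1 from 387 ± 39.9 to 183 ± 24.9 CPM (−1.08 ± 0.0756, n = 4, adjusted p = 1.2e-08). Targets of p53 fell in 13 of 26 cases and 0 rose (median −0.24, list adjusted p = 0.00064), CDKN1A from 150 ± 17.4 to 61.8 ± 5.44 CPM (−1.28 ± 0.0793) and MDM2, the p53 ubiquitin ligase, with −0.48. Interferon-stimulated genes fell in 10 of 15 cases (median −1.60, list adjusted p = 0.0756), IFIT3 (−3.72), and myeloid genes in 9 of 16 (median −0.33, list adjusted p = 0.0111), FCGR1A (−0.55) and the receptor TLR4 (−0.70). WDR5 complex partners had 4 of 18 higher, KMT2B by 0.27 (median 0.13, list adjusted p = 0.137). KLF2, a transcription factor, rose from 3.19 ± 0.311 to 8.05 ± 0.827 CPM (1.34 ± 0.136), with FOSB, ARTN and SOCS1 (0.97, 0.76 and 0.74). The largest falls were those of SPP1 (−6.17 ± 1.05, adjusted p = 0.00197), CSF1 (−4.51), IL4I1 (−3.51) and SLC6A8 (−3.20), and DMSO libraries spread widely in them, SPP1 at 15.0 ± 15.1 CPM.

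Ribosomal protein genes fell with venetoclax in 41 of 79 cases, or 53 when adjusted over the list alone, by small amounts (median −0.17, list adjusted p = 0.358), RPS3A (−0.41). Translation factors had 10 lower and 2 higher of 42, EIF2S3 at −0.25 and EIF4A1 at 0.38, stress response targets 7 lower and 1 higher (TRIB3 −1.17, list adjusted p = 0.358), and cell cycle genes 7 of 26 higher (CENPF 0.26, list adjusted p = 0.612). BCL2 rose by 0.20 ± 0.0428 (adjusted p = 0.00217), the only rise among 13 BCL2 family genes, with BMF at −0.18, and FLT3 fell by 0.24. Mitochondrial mRNAs had 5 of 13 higher (median 0.88, list adjusted p = 0.358), and their share of protein-coding counts was 0.444% to 0.835% in DMSO and 0.701% to 1.44% with venetoclax. WDR5 had 0.14 ± 0.0541 (adjusted p = 0.0925). In all 907 genes rose and 1202 fell, and with only the compared groups 498 and 733, SPP1 (adjusted p = 0.0535) and SLC6A8 (0.0786) no longer passing. Without DMSO replicate 2 or 3 or venetoclax replicate 1, 495, 504 and 553 rose, and without DMSO replicate 2 767 fell. BMF, BOP1 (0.23), TCOF1 (0.22) and MRPS35 (−0.18) each lost the call without DMSO replicate 2 (adjusted p 0.08 to 0.0914). BMF lost it also without DMSO replicate 1 (0.158) or venetoclax replicate 2, 3 or 4 (0.0662 to 0.0849), BOP1 without DMSO replicate 1 (0.132) or 3 (0.0856) or venetoclax replicate 1 (0.164) or 4 (0.102), TCOF1 without DMSO replicate 1 (0.0961) or 3 (0.0695) or venetoclax replicate 1 (0.11), and MRPS35 without DMSO replicate 3 (0.0647) or venetoclax replicate 1 (0.0724).

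C10 was set against the same DMSO in MV4:11. Genes that fell were RPL6, from 1035 ± 45.7 to 519 ± 16.1 CPM (SE 0.0498 on the log2 scale, n = 4, adjusted p = 5.81e-13), RPL29 (−0.97), RPL34 (−0.91), EEF2 from 6783 ± 257 to 4333 ± 254 CPM, and RRM2, a subunit of ribonucleotide reductase, from 396 ± 9.05 to 213 ± 3.11 CPM. Ribosomal protein genes had 44 of 79 lower and 21 higher, or 24 higher when adjusted over the list alone (median −0.38, list adjusted p = 0.354), while all 26 cell cycle genes fell (median −0.73, list adjusted p = 0.00386). So did 51 of 55 histone genes (list adjusted p = 0.0564) and all 15 cholesterol synthesis genes (median −0.80, list adjusted p = 0.023). Targets of p53 rose in 21 of 26 cases and 1 fell (median 0.43, list adjusted p = 0.000995), with ZMAT3 from 32.2 ± 2.64 to 87.1 ± 5.3 CPM (1.43 ± 0.0696) and TP53INP1 at 1.12. Stress response targets fell in 10 of 15 cases (median −0.41, list adjusted p = 0.0705), PHGDH, the first enzyme of serine synthesis, −2.15 ± 0.0882, and aminoacyl-tRNA synthetases in 11 of 23 (AARS1 −0.79, list adjusted p = 0.68). Myeloid genes had 7 of 16 higher and 2 lower (median 0.14, list adjusted p = 0.157), S100A8 from 5.48 ± 0.112 to 12.8 ± 1.22 CPM and S100A9 by 1.15.

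Further genes that rose with C10 were JAML (1.33), NAIP (1.19) and FOS (1.07), and SPP1 (−6.34), CSF1 (−5.50), SLC6A8 (−3.79) and OCSTAMP (−3.53) had the largest falls. The BCL2 family had 6 of 13 higher, the proapoptotic BCL2L11 and BAX by 0.36 and 0.40, and BCL2 itself fell by 0.23 ± 0.043 (adjusted p = 0.000169). Respiratory chain genes had 34 of 76 higher, ATP5F1E by 0.41 (list adjusted p = 0.68), and mitochondrial mRNAs 12 of 13 (median 0.92, list adjusted p = 0.68), with a share of counts of 0.962% to 1.43%. Ribosome biogenesis genes had 11 lower and 2 higher (NPM1 −0.32, TCOF1 −0.37), mitochondrial ribosomal proteins 12 and 4 of 77 (MRPS23 0.37), interferon-stimulated genes 8 and 2 (IFIT3 −2.39, list adjusted p = 0.846), translation factors 9 and 5, and MLL fusion targets 0 and 2 of 10. WDR5 fell by 0.19 ± 0.0546 (adjusted p = 0.00769). In all 2398 genes rose and 2450 fell. PBX3 (0.15) no longer passed without C10 replicate 1 (adjusted p = 0.0506) or DMSO replicate 3 (0.0647).

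With both drugs RASD1, a RAS family gene, rose from 1.12 ± 0.447 to 15.2 ± 2.18 CPM (3.75 ± 0.174, n = 4, adjusted p = 8.99e-14), KLF2 from 3.19 ± 0.311 to 21.6 ± 3.38 CPM, the kinase gene SGK1 by 3.07 and KIF1A by 2.80, and the immediate early gene FOSB from 7.28 ± 1.07 to 34.3 ± 3.92 CPM. Ribosomal protein genes had 50 of 79 lower and 0 higher, or 2 higher when adjusted over the list alone (median −0.66, list adjusted p = 0.0612), RPL34 from 389 ± 7.49 to 167 ± 5.6 CPM (−1.22 ± 0.049) and RPL6 (−1.23). All 15 cholesterol synthesis genes fell (median −1.09, list adjusted p = 0.0119), 25 of 26 cell cycle genes fell (RRM2 −0.75, list adjusted p = 0.0432) and 49 of 55 histone genes fell with 2 higher (list adjusted p = 0.134). Targets of p53 had 14 of 26 higher and 2 lower (list adjusted p = 0.0432), ZMAT3 by 0.96, and the BCL2 family 7 of 13 higher (list adjusted p = 0.174), with the proapoptotic BBC3 from 24.5 ± 1.99 to 46.2 ± 5.94 CPM and PMAIP1 by 0.88. BCL2 had −0.06 ± 0.0429 (adjusted p = 0.235) and WDR5 −0.12 ± 0.0545 (adjusted p = 0.0828). Immediate early genes had 6 of 12 higher and 4 lower (list adjusted p = 0.163), stress response targets 10 lower (PHGDH −2.07, list adjusted p = 0.174), aminoacyl-tRNA synthetases 14 of 23 lower (AARS1 −0.88), myeloid genes 6 higher and 5 lower (S100A8 1.47), interferon-stimulated genes 9 lower and 3 higher, and MLL fusion targets 4 lower and 1 higher (HOXA10 −0.34, FLT3 −0.34). In all 2902 genes rose and 2873 fell, SPP1 (−6.32), CSF1 (−5.23), SLCO4C1 (−3.89) and OCSTAMP (−3.44) most.

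**Figure D3:**
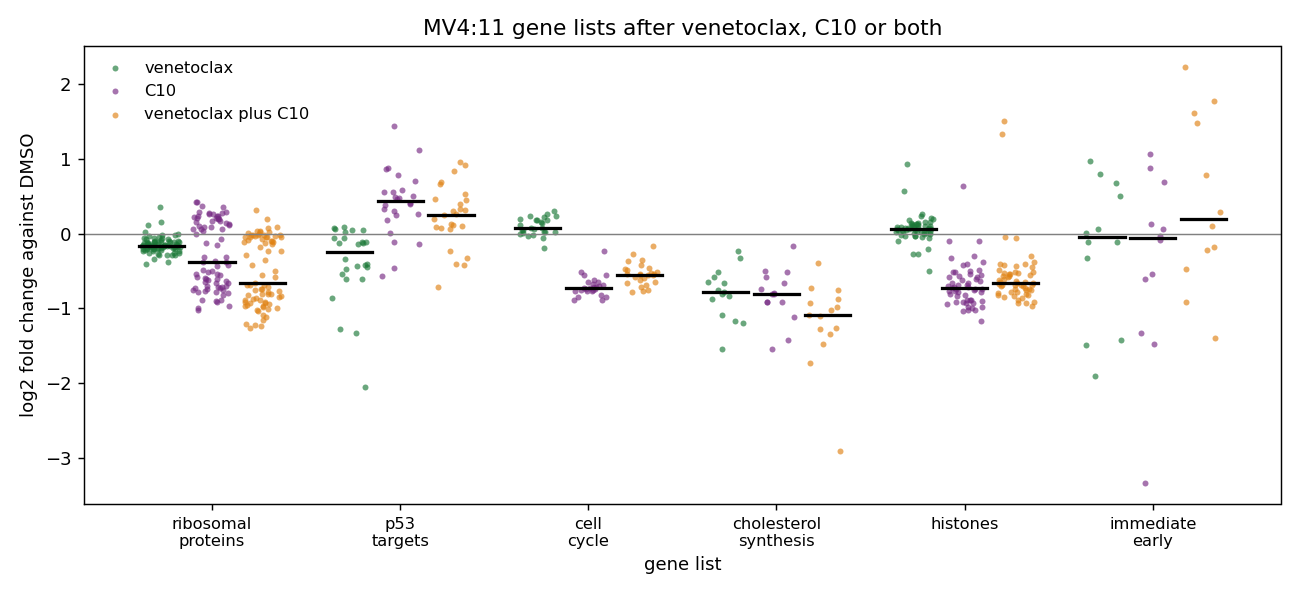
Log2 fold changes against DMSO of the members of 6 gene lists in MV4:11 cells after venetoclax, C10 or both; points are genes and black lines are list medians. The median of the p53 targets is −0.244 after venetoclax, 0.432 after C10 and 0.255 after both, and that of the cholesterol synthesis genes is below 0 after each treatment.

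The combination was also set against each drug. Against venetoclax, HMOX1, the heme oxygenase of oxidative stress, was higher, at 34.5 ± 2.21 against 5.73 ± 0.772 CPM (2.59 ± 0.461, n = 4, adjusted p = 0.000663), with KIF1A (2.34), while IGLL1 (−2.39) and PHGDH (−2.23) were lower. Targets of p53 were higher in 21 of 26 cases (median 0.64, list adjusted p = 0.000178), all 26 cell cycle genes were lower, and 45 ribosomal protein genes were lower and 7 higher (list adjusted p = 0.168), among 2579 higher and 2391 lower genes. Against C10, RASD1 (2.34 ± 0.155) and SGK1 (2.22) were higher and the NAD glycohydrolase gene CD38 (−1.54) and SEL1L3 (−1.50) lower. Ribosomal protein genes were lower in 65 of 79 cases, or 71 when adjusted over the list alone (median −0.24, list adjusted p = 0.0855), p53 targets in 12 with 2 higher (list adjusted p = 0.0113), and immediate early genes were higher in 8 of 12 with 1 lower (list adjusted p = 0.0113). The 795 genes higher than with C10 became 529 without combination replicate 3, and 805 were lower.

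Whether the combination differed from the sum of the single log2 effects was tested as an interaction, for which chance was not excluded. Of 100 splits of the samples 5, the real one among them, gave at least as many genes. The splits mixed libraries of all groups, so they can carry the effect of a drug alone and cannot decide this question. HMOX1 (4.11 ± 0.645, adjusted p = 0.00619) and IL4I1 (3.63 ± 0.609) lay above the sum, and SEL1L3 (−1.04 ± 0.0847, adjusted p = 1.94e-07) and GIPC3 (−0.86) below it. A high DMSO level enters this test with a positive sign, and IL4I1 was at 102 ± 52.9 CPM in DMSO, so its value depends on these libraries. Cholesterol synthesis genes lay above the sum in 8 of 15 cases, or 12 when adjusted over the list alone (median 0.48, list adjusted p = 0.0413), interferon-stimulated genes in 4 of 15, or 12 over the list alone (median 1.12, list adjusted p = 0.0413), and immediate early genes in 6 of 12 (median 0.52, list adjusted p = 0.0305). Cholesterol synthesis and interferon-stimulated genes were mostly lower than DMSO after each treatment. A high DMSO level would give such positive values, so the limit stated for IL4I1 holds for these lists too. No ribosomal protein gene passed in edgeR's interaction test, with a median of −0.07. In all 205 genes lay above and 35 below, with 1512 at an unadjusted p under 0.05, and 330 and 78 with DESeq2. The higher count was 129, 117 and 401 without DMSO replicates 1, 2 and 4 and 103 without combination replicate 1. The lower count was 16, 20 and 74 without DMSO replicates 2, 3 and 4, 21, 20 and 22 without C10 replicates 1, 2 and 3, and 23 without combination replicate 4. GIPC3 lost its call in 10 of the 16 fits that leave out a library, with adjusted p from 0.0534 to 0.123: without combination replicate 1 or 3, C10 replicate 1, 3 or 4, DMSO replicate 2 or 3, or venetoclax replicate 1, 2 or 4.

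Fold changes of the 3 MV4:11 treatments share their DMSO libraries. Across genes, which are not independent replicates, C10 and the combination correlated with r = 0.800, venetoclax and the combination with r = 0.571, and venetoclax and C10 with r = 0.417. In 10 simulations of unchanged groups the shared controls alone gave r = 0.488, 0.502 and 0.497. The observed covariance exceeded the simulated one by 0.165, 0.0846 and 0.0487 in the order of the pairs just named. The simulations held no drug effect, so hardly any gene could be called in them. Their 0 shared calls therefore cannot tell whether shared controls enlarge the overlaps of called genes. With DMSO split between the comparisons, r was 0.567 to 0.699, 0.298 to 0.4996 and 0.188 to 0.296. C10 and the combination shared 1817 higher genes (520 expected for independent lists) and 1917 lower (526 expected), venetoclax and the combination 534 and 661 (197 and 258 expected), and venetoclax and C10 302 and 408 (163 and 220 expected). With DMSO split, the counts were 1048 to 1166 higher and 1353 to 1454 lower, 89 to 286 and 292 to 429, and 53 to 139 and 191 to 274, in the same order. These fits held fewer DMSO libraries and no expected counts were computed for them, so they cannot be set against the expected counts above.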

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

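All tests of explanations in this part were chosen only after the results were seen, and the comparisons between groups were planned. The differences between groups came from interaction tests fixed in advance. The C6 effect differed between 1 and 4 days for 7406 genes. In MV4:11 the interaction test called 240 genes, with medians of 0.477 for cholesterol synthesis, 1.12 for interferon-stimulated and 0.518 for immediate early genes, but chance cannot be excluded there. The cholesterol synthesis and interferon-stimulated medians also depend on the DMSO level, since both lists were mostly lower than DMSO after each treatment.

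The first pattern weighed is the fall of the 4 heat shock genes with the largest falls after 4 days of C6, and of ribosomal protein genes. The 4 genes with the largest falls had a median rise of 2.49 on the log2 scale from 1 day to 4 day DMSO, so a rise in the 4 day control may account for much of their fall. DNAJB1 was at 44.55 to 57.77 CPM after 4 days of C6 and 92.53 to 97.79 in 1 day DMSO, so it lay below that control too. Of the 4 genes only HSPB1 lost its call against 1 day DMSO (−0.58, adjusted p = 0.0577). HSPA6, HSPA1B and HSPB1 were near or under 5 CPM in both groups, so their differences are less certain. These groups also differ in time, so whether C6 caused the remaining difference stays open. Ribosomal protein genes had a median of −0.5 against 1 day DMSO, so the rise of the control does not account for their whole fall either, though it is part of the −1.25 against 4 day DMSO. A biological effect of C6 at 4 days and the handling of the 4 day cultures both stay open.

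The second pattern is the rise of mitochondrially encoded mRNAs after 4 days of C6. Without C6 replicate 3, whose share of these mRNAs was 1.321%, the list median was 1.68, so that library alone is not the whole cause. The list fell by 1.67 from 1 day to 4 day DMSO (−1.67), which is as large as the median without replicate 3, so a fall in the 4 day control may account for most of the rise. Set against 1 day DMSO the median was 0.793 with 1 gene higher. C6 replicates 1 and 2 had shares of 0.306% and 0.285%, near the 0.262% to 0.278% of 1 day DMSO, so this median leans on replicate 3. A C6 effect on these mRNAs stays open.

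The third pattern is that genes at least 2-fold lower after each MV4:11 treatment, such as SPP1 and CSF1, vary among the DMSO libraries themselves. Over 80 such genes DMSO replicates 1, 2 and 3 kept 155%, 123% and 91.8% of the median log2 gap to the treated groups, and replicate 4 kept 48%. The bound set for this test was 50%, so the value is close to it. A candidate explanation is that the DMSO cultures differed in state, which would make the size of these falls depend on the DMSO library. Replicate 4 still lay above the treated groups, so an effect of the drugs stays open.

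Whether other splits of the samples give as many genes was counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real split and the highest other gave 31 and 0 genes for C6 at 1 day, 9723 and 0 for C6 at 4 days, 4862 and 0 for dTAG47, 3465 and 0 for C38b, 971 and 1 for C38b against C6, 77 and 0 for LoVo T>C reads, and 48 and 2 for all LoVo reads. In the comparisons whose numbers pair the samples, C6 at 4 days and dTAG47, 4 splits part all 3 pairs as the real one does, and the highest of the others among them was 0. In MV4:11 the real split was the only 1 of 35 to reach its count. The counts were 2109 for venetoclax (highest other 404), 4848 for C10 (1) and 5775 for both drugs (0). They were 4970 for both against venetoclax (963) and 1600 for both against C10 (0). A chance split of these libraries is thus unlikely to give the calls, with no adjustment over comparisons. Nothing says that these replicates were separate cultures, so a chance difference between cultures is not excluded. For the difference between the C6 times 1 of 100 splits, the real one, reached 7406, with 6535 the highest other. These splits shuffled C6 and DMSO within each time, without regard to the pairing at 4 days. They thereby removed the C6 effect of each time too, so they cannot tell whether the difference between times is chance. Of the other splits 7 passed 1000. A split that keeps the real grouping at 4 days still carries the 4 day C6 effect, so high counts can follow from the design. What these splits have in common was not tested. For the MV4:11 interaction 5 of 100 splits, the real one among them, gave 240 genes or more, the highest 3551, and 4 others than the real one passed 1000. These splits mixed libraries of all groups, so a split can carry the effect of a drug alone. They cannot decide whether the interaction is chance, and chance was not excluded by another test. What these splits have in common was also not tested.

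Single libraries that lay far from the other 3 of their MV4:11 group were found for 12 of 256 combinations of gene and group, about the 1 in 20 that chance gives. With both drugs FOSB was at 28.44 CPM in replicate 3 (others 36.19 to 36.32) and SGK1 at 7.156 in the same replicate (10.19 to 10.48). TAF1D was at 100.7 in combination replicate 2 (81.96 to 84.66) and BAX at 219.2 there (253.1 to 257.8), while HOXA10 was at 35.87 (28.95 to 29.91) and MRPS27 at 97.68 (93.08 to 93.86) in combination replicate 1. In venetoclax replicate 1 MDM2 was at 143.3 CPM (165.4 to 166.9), BMF at 50.46 (46.79 to 47.18) and KMT2B at 295 (251.1 to 256.7), and in venetoclax replicate 2 INSIG1 was at 220 (168.4 to 173.1). In DMSO replicate 1 PHGDH was at 61.05 CPM (72.69 to 74.88) and RASD1 at 1.788 (0.8744 to 0.914).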

How the results depend on the processing

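The other control times, protein-coding genes only, the larger overlap for bound genes, C6 at 4 days beside C38b and RLE for ribosomal protein genes with and without a peak were chosen only after the results were seen, and the other alternatives before. Of the values per named gene 3010 stayed on their side of the threshold, 157 no longer passed, 17 newly passed and 13 changed sign, and of the list medians 3603, 87, 114 and 11. The count of C6 at 1 day moves with each library, and that of C38b with each but C38b replicate 1. The cause was not tested for the values below. Leaving out a replicate was not possible for LoVo peaks, which have 2.

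With the replicate number as a block, C38b against C6 gave 215 higher and 269 lower, C6 at 1 day 2 higher, and all LoVo reads 48 and 112, in comparisons where the numbers did not pair the libraries. Where they did, the block gave 4871 and 4792 for C6 at 4 days and 2962 and 3334 for dTAG47. The unpaired main fits gave 4948 and 4775 for C6 at 4 days and 2180 and 2682 for dTAG47. List counts, overlaps and the split of ribosomal protein genes rest on these unpaired fits. No named gene of these comparisons lost its call with the block. DESeq2 gave 59 and 58 for C6 at 1 day, 91 lower for all LoVo reads, and 330 and 78 for the MV4:11 interaction. No filter on low counts gave 47 and 102 for C6 at 1 day, with an MLL target median of −0.1469, and 39 and 126 for all LoVo reads. Only the compared groups gave 626 and 574 for C6 at 1 day and 498 and 733 for venetoclax. T>C reads scaled by the gene's own total gave 8 and 35, and TMM on the T>C reads themselves gave a translation factor median of 0.01452.

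With C6 at 4 days beside C38b the difference gave 3294 and 3406 genes and medians of −0.5019 for aminoacyl-tRNA synthetases, −1.994 for stress response targets and −0.3943 for mitochondrial mRNAs. C38b against 4 day DMSO gave 3983 and 3858, BAX at 0.4414, GARS −0.5045, MRPL42 −0.1682, NOB1 −1.13, PSAT1 −0.4665 and TAF1D −0.6012, and medians of −0.5042 for synthetases and −0.1167 for translation factors. C6 at 4 days against 1 day DMSO gave CHGB −0.09443, EEF2 0.07648, EPB41L4A-AS1 0.7836, FOSL2 −0.4903, NDUFV2 0.2142, NOB1 0.821 and WDR5 −0.5135, and a synthetase median of 0.5472.

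With an estimated correlation the ribosomal protein list no longer passed for C38b (median −0.3741), the difference between C6 times (−0.7894), C6 at 1 day (−0.2921) and 4 days (−1.25), dTAG47 (−0.237), C10 (−0.3765), the MV4:11 interaction (−0.07408) and venetoclax (−0.1662).

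With an overlap of at least 50% of both peaks, LoVo had 63 regions and 25 bound ribosomal protein genes, and with a peak in every replicate MC38 had 1529 regions and 3T3 1249. Genes with a peak in any LoVo replicate had medians of −0.007892 in all LoVo reads, 0.0298 for C38b, 0.01741 for C6 at 1 day and 0.001742 for dTAG47, but those with a peak in any Be2C replicate, the line used for CHP134 in the report, had −0.1475, −0.08996 and −0.1101. With a peak in any replicate of each human line the venetoclax median was −0.01388, and without ribosomal protein genes the venetoclax median was 0.02096. At an adjusted p under 0.01, lower genes shared were 6 for C6 at 1 and 4 days, 5 for C6 at 1 day and dTAG47, 2 for it and LoVo T>C reads, 3 for it and C10, 415 for C6 at 4 days and dTAG47, 549 for it and C10, and 278 for dTAG47 and C10. Higher genes shared were 0, 1 and 0 for C6 at 1 day with C6 at 4 days, dTAG47 and C10, 169 and 265 for C6 at 4 days with dTAG47 and C10, and 0 and 184 for dTAG47 with LoVo T>C reads and C10. With DMSO split in MV4:11, C10 and the combination shared 1048 to 1166 higher genes, venetoclax and C10 53 to 139 higher and at least 191 lower, and venetoclax and the combination 89 to 286 higher and 292 to 429 lower.

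Leaving out each library in turn gave these ranges: C38b against C6 103 to 1166 higher and 121 to 1195 lower, with a ribosomal protein median of −0.05223 to 0.05201; C38b 543 to 2941 and 727 to 2998; C6 at 1 day 0 to 1 and 3 to 5, with a mitochondrial ribosomal protein median of −0.006573 to 0.07002; and all LoVo reads 9 to 14 and 5 to 101. In MV4:11 they were 103 to 401 and 16 to 74 for the interaction, with a histone median of −0.03453 to 0.08137, 529 to 737 higher for both drugs against C10, and 495 to 1060 and 767 to 1225 for venetoclax. Consensus regions ranged from 1818 to 2161 in MC38, from 1316 to 2130 in 3T3 and from 86 to 114 in Be2C, where 42 ribosomal protein genes stayed bound each time.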

Other observations

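No test of an explanation in this part was planned, and the values were looked at only after the results were seen. Further lists describe what else moved. Of 51 histone genes 6 rose after C38b with 0 lower (list adjusted p = 0.885), and of 49 after dTAG47 20 fell with 2 higher (list adjusted p = 0.87), a difference that was not tested. Histone genes took 3.25%, 3.15% and 2.64% of protein-coding counts with C38b, 2.87% to 3.34% with C6 at 1 day and 1.09% to 1.69% with C6 at 4 days. The ribosomal protein share was 6.04%, 5.97% and 5.20% with C38b and 5.59% to 6.42% with C6 at 1 day. Among lists that fit other cell types, fibroblast markers had 2 higher and 2 lower of 5 after dTAG47 and 1 lower of 4 after C6 at 4 days, epithelial markers 1 higher of 3 after dTAG47, and lymphoid or erythroid markers 1 higher of 2 after venetoclax and 1 lower of 2 after C10. Myeloid genes, few of which are detected in CHP134, had 2 higher of 5 after C6 at 4 days, and MLL fusion targets 4 lower of 8.

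In MV4:11, mesenchymal list genes had 4 higher and 1 lower of 9 with both drugs (median 0.43, list adjusted p = 0.385), and 3 higher and 1 lower of 9 with C10. WNT targets had 3 higher and 2 lower of 8 with both drugs, and respiratory chain genes 19 higher and 2 lower of 76, NDUFA12 by 0.33. With both drugs mitochondrial ribosomal protein genes had 26 lower and 5 higher of 77, MRPS27 at −0.41, translation factors 17 lower and 4 higher of 42, EIF4A1 at 0.71 and EEF2 at −0.87, and ribosome biogenesis genes 13 lower and 1 higher of 32, NPM1 at −0.41. All 13 mitochondrially encoded mRNAs rose (median 1.15, list adjusted p = 0.581), with a share of protein-coding counts of 1.04% to 1.81% against 0.444% to 0.835% in DMSO. Adrenergic genes, a neuroblastoma list, had 1 lower of 7 in MV4:11 after each treatment.

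In the CHP134 tables of C6 and DMSO short noncoding RNAs took 11.4% to 28.3% of all counts and the 10 highest genes 16.4% to 32.8%. All 3 DMSO 4 day libraries (24.0% to 28.3%, and 28.8% to 32.8%) lay above all 6 libraries of 1 day, so the control of C6 at 4 days differs in composition from that of 1 day. C6 4 day replicate 1 (26.95% and 31.25%) lay within the range of 4 day DMSO, so this is not particular to the control. Replicate 2 (22.38% and 26.84%) lay below that range, and replicate 3 had the lowest shares.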
